A study of Mus musculus with 8 samples.

How the data were processed

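The study measured 5-hydroxymethylcytosine by hMeDIP-seq in mouse cells. Of 8 samples, 6 were hMeDIP libraries with processed files, 1 each of MEFs, induced neurons at 1, 3, 5 and 7 dpi and primary neurons, and 2 were inputs without a file of their own here. Groups were taken from the titles and source names, and every column used was tied to its library by the code in its own header. The labels give these codes, but those of the 3, 5 and 7 dpi samples name the code of primary neurons for a hyper list. The headers were followed there. Each file was used as deposited, with 1 peak list per hMeDIP library and 10 promoter lists, a hyper and a hypo list for each of the 5 comparisons with MEFs. Per the submitters' processing notes, CASAVA and Bowtie2 2.1.0 were used with the mm10 genome build. The peak caller, the differential caller, their settings and the input used for each library were not given in the sources used here.

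The fold enrichment of each peak is a ratio that the authors deposited, with its background not given in the sources used here. The signal at each peak summit is a whole number of tags, per the file headers and values. The deposited column headed q-value in the peak lists held values above 1, at least 4.02, and was read as −log10 of q. In the promoter lists the authors gave a p-value and a q-value per region, which set 1 library against 1 library and so compare libraries, not conditions. In the authors' deposited table the highest p-value was 0.0105 and the highest q-value 0.101. The promoter signal that the authors deposited under the name count was not whole. It was made of whole reads multiplied by 1 factor per library and comparison, as found from the values: division by that factor gave whole numbers within 0.1 for 100% of values in all columns but 1, where 99.95% did. These recovered reads give the depth behind each region, and no count model was fitted, since no group had replicates.

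Everything else was computed with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with seed 1 for all random draws. Peaks listed for several genes were counted once. Overlap meant at least 1 bp in common. Expected overlaps came from 100 shuffles of the peaks within their chromosomes, or from placing promoter regions around random TSSs. These were the TSSs given in the deposited lists themselves, not those of an outside annotation, and they also defined which peaks lay near a TSS. The background for gene lists was 26219 RefSeq genes (GRCm38.p6, the assembly of mm10). Shares have exact Clopper-Pearson intervals and ratios of reads exact conditional Poisson intervals, both at 95%. A fold against 0 reads was computed at a floor of 3 reads per library and is written as at least that fold. It takes the reads of the other library as exact, so it is not the lower limit of a counting interval, which can be lower. With 1 to 3 reads in the lower library the interval of the ratio is wide, and it is given for some of these ratios only.

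For 21 gene lists the number of members in a promoter list or with a peak was ranked among 10000 random lists of the same size, and counts outside percentiles 2.5 to 97.5 were taken as standing apart. The lists were pan-neuronal genes, neurogenic transcription factors, glutamate receptors and excitatory synapse, inhibitory synapse, voltage-gated ion channels, axon guidance, fibroblast identity and extracellular matrix, Hox genes, DNA modification machinery, cell cycle, pluripotency and germline, astrocyte, oligodendrocyte, microglia and blood and endothelial markers, skeletal muscle, housekeeping, imprinted genes, protocadherins, olfactory receptors, and keratins and skin genes. This made 105 counts per direction for promoters and 126 for peaks. Because the 5 comparisons share the MEF library, unchanged libraries were simulated as Poisson draws against its reads. The chance of a call, and of a shared call, with the MEF reads drawn as well was added after the results were seen. The gene lists, the tests of the comparisons, the rule for naming genes and most alternative settings were fixed before the data were examined. The tests of explanations in the closing section were not.

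Named genes followed a rule with 6 parts. They were, per comparison and direction, the 5 regions with the largest fold among those at or above the list's median in the higher library, without symbols of predicted genes; up to 4 members per described gene list with the largest fold; the 10 genes per direction with the largest smallest fold among those listed the same way in all 5 comparisons; the 3 peaks per library with the highest fold enrichment and a gene symbol; the 5 genes in opposite lists at 7 dpi and in primary neurons with the largest difference; and the DNA modification genes with 11 fixed genes. Because 0 reads are held at the floor, the largest folds fall mostly on regions with 1 read in the lower library. Genes named outside the rule are said to have been chosen after their values were seen, and some genes that the rule takes are not reported here.

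The procedures were tested on simulated data first. Reads were recovered in 100% of 11313 simulated values of the 7 dpi hypo list. Gene lists planted at double the share were placed above the central range in 100% of cases, and random lists fell outside it in 7.5%. A planted overlap of 50% of the 1579 peaks at 7 dpi was measured as 50.1%.

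The alternatives were stricter peak thresholds (fold enrichment of at least 10, or a −log10 q of at least 27.9, the strictest part of its range), merging peaks within 1000 bp, autosomes only, 50% coverage for overlap, a MEF list limited to the size of the other, gene symbols in place of regions, an absolute log2 fold of at least 2, p below 1e-10, recentred folds, a background of named genes, length-matched random lists and genes in both lists left out. Those chosen after seeing the data were at least 15 reads in the higher library, reads without scaling, peaks over 500 tags left out, multi-copy loci left out, peaks on MEF peaks left out, and shuffled peaks or draws of MEF peaks in place of random lists. Multi-copy loci were judged only by reads in the lower library and by loci listed for several genes, not by sequence. Random lists matched on promoter CpG content were not run, since no genome sequence was used here.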

Results

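5-Hydroxymethylcytosine, an oxidised form of methylated cytosine in DNA, was profiled by hMeDIP-seq, in which DNA fragments that carry the mark are captured with an antibody and sequenced. The cells came from mice of the ICR strain and followed the conversion of fibroblasts into neurons. There were 6 such libraries, 1 per group: mouse embryonic fibroblasts (MEFs) from E13.5 embryos, induced neurons made from MEFs at 1, 3, 5 and 7 dpi (a unit that the labels do not spell out), and primary hippocampal neurons from 1-day-old pups. The submitters named MEFs as the negative and primary neurons as the positive control. A further 2 input libraries, 1 of MEFs and 1 mixed, were not analysed on their own here. No group had replicates, so each difference is one between single libraries, has no replicate check and carries no p-value across genes. Total reads per library were not given in the sources used here. In the promoter lists a read of the other library was worth 1.78 times a MEF read at 1 dpi, 1.75 times at 3, 5 and 7 dpi and 1.80 times in primary neurons. All intervals are exact at 95% and cover counting error only.

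The peaks with the highest fold enrichment lay at single loci, most of them away from promoters. The same intergenic place near 3110001I22Rik, on chromosome 16 from 13695128 to 13696495 (mm10) in the MEF list, was among the 3 most enriched peaks with a gene symbol in all 6 libraries. It lay 23.9 kb from the transcription start site (TSS), and its fold enrichment was 21.2 in MEFs, 12.2, 23.9, 23.4 and 26.6 at 1, 3, 5 and 7 dpi and 15.2 in primary neurons. The body of Cdk8, a kinase of the Mediator complex, held a leading peak at 1 dpi (fold enrichment 10.1, chromosome 5 from 146260643 to 146261224) and at 3 dpi (14.6). Other leading peaks lay in the bodies of Pdzk1, which encodes a scaffold protein (15.3 at 3 dpi), and Thada (16.1 at 5 dpi, chromosome 17 from 84461333 to 84464207). Intergenic ones were closest to Trim56 (14.3 at 5 dpi), to Alx4, a homeobox gene of skull and limb development (21.5 at 7 dpi), and to Cyp51, a gene of cholesterol synthesis (15.4 in primary neurons). In MEFs the leading peaks were assigned to D5Ertd579e (23.6, chromosome 5 from 36707559 to 36708842) and, from 716 kb away, to Zc3h15 (22.8). The fold enrichments and tag counts of peaks are the authors' own and describe peaks within a list.

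The 6 libraries differed most in how many places were listed. The MEF list held 176853 peaks that covered 90.2 Mb. The lists of induced neurons held 262, 1238, 1100 and 1579 peaks at 1, 3, 5 and 7 dpi, and that of primary neurons 549, covering between 0.156 and 1.14 Mb. MEF peaks were 112 to 675 times as many as those of any other library, although the median fold enrichment was similar, at 4.54 in MEFs and 4.78 to 5.60 elsewhere. In MEFs 86.7% of peaks had the shortest length in the lists, 480 bp, against 50% at 1 dpi and 10.6% at 7 dpi. With peaks of at least 10-fold enrichment only, 1808 were left in MEFs, 2, 11, 20 and 49 at the 4 days and 10 in primary neurons.

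**Figure D1:**
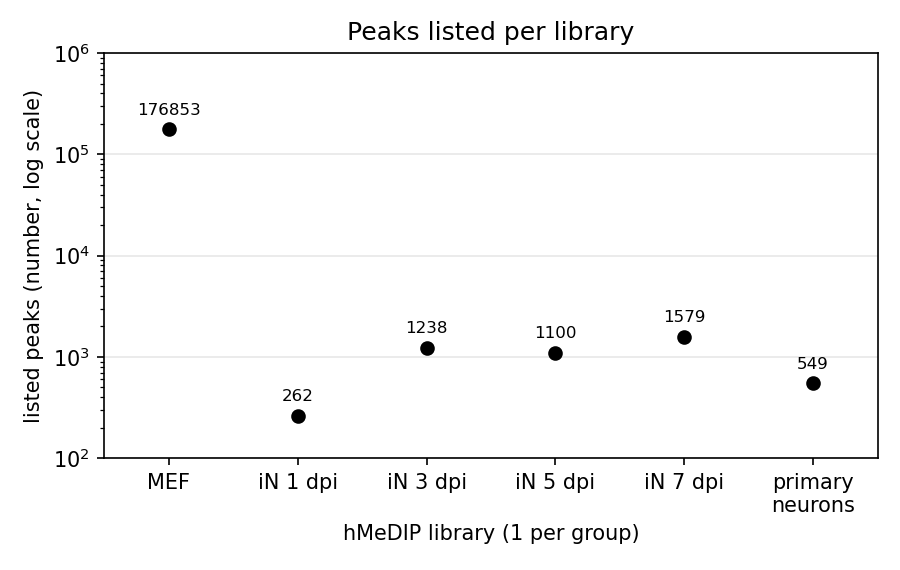
Number of peaks listed for each of the 6 hMeDIP libraries, as points on a log axis. The MEF library holds 176853 peaks and the other 5 hold between 262 and 1579.

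Promoters held few of the peaks in any library. Peaks that the authors' annotation placed at promoters made up 3.24% in MEFs, 1.15, 1.94, 2 and 2.72% at 1, 3, 5 and 7 dpi, and 1.09% in primary neurons, with upper bounds of the intervals at 3.33, 3.31, 2.87, 3.01, 3.65 and 2.36%. Gene bodies held 24.4% in MEFs and 21.8 to 27.0% elsewhere, and the rest was intergenic. Exons and introns were not told apart in the annotation. Peaks placed at random on the same chromosomes fell within 2000 bp of a TSS in 3.13 to 3.38% of cases, which is above the upper bound in MEFs (3.35% against 3.33%), in primary neurons and at 3 and 5 dpi. With peaks of at least 10-fold enrichment only, the share at promoters was 1.94% in MEFs and 2.04% at 7 dpi, or 1 of 49 peaks, and none of the 2, 11 and 20 peaks at 1, 3 and 5 dpi and the 10 in primary neurons lay there.

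Peaks assigned to neuronal, endothelial and imprinted genes were few in the induced neurons, and the groups that stood out depended on the comparison used. The authors' annotation assigns each peak to a gene, which for an intergenic peak can lie far away, and a gene counts here when a peak was assigned to it. Glutamate receptor and excitatory synapse genes had peaks in 6, 5 and 7 of 41 members at 3, 5 and 7 dpi, which lay at percentiles 99.7, 99.4 and 99.9 of 10000 random lists of the same size. Such genes are long, and among random lists matched on gene length the percentiles were 96.1, 93.9 and 96.1. The same numbers of peaks drawn from the MEF list would touch 5.88, 5.38 and 7.05 members on average. Rbfox3, which encodes the neuronal splicing factor NeuN, was chosen here after its values were seen. It had peaks in the gene body at 3 dpi (chromosome 11 from 118822755 to 118823389, fold enrichment 6.70) and 7 dpi (8.23) that met no MEF peak, and peaks at 5 dpi (7.74) and in primary neurons (6.56) that did. Endothelial markers had peaks assigned to 4 of 14 members at 5 dpi and 3 in primary neurons, against 0.958 and 0.435 for draws of MEF peaks. At 5 dpi a peak lay in the body of the VEGF receptor gene Flt1 (fold enrichment 5.13). Intergenic peaks were assigned to the VEGF receptor gene Kdr from 147 kb away (5.57, chromosome 5 from 75830891 to 75831496), to the transcription factor gene Erg from 65.8 kb (5.34) and to Vwf, which encodes von Willebrand factor, from 28.2 kb (5.89). In primary neurons a peak lay in the body of Cdh5, which encodes the adhesion molecule VE-cadherin (6.43), and intergenic ones were assigned to Sox17 from 87.6 kb (6.25) and to Erg from 72.9 kb (4.22). Imprinted genes, which are expressed from the allele of a single parent, had peaks in 4 of 35 members at 5 dpi (percentile 98.0, 97.8 when length-matched and 98.5 against shuffled positions), a count that did not stand apart from draws of MEF peaks (1.815 on average). Peaks lay in the bodies of Gnas (6.14, chromosome 2 from 174304530 to 174305009) and Zim1 (6.04), and an intergenic one was assigned to Peg13 from 27.9 kb (4.89). These members were also chosen after their values were seen.

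Few peaks were assigned to olfactory receptor and protocadherin genes, both arranged in clusters, at 5 and 7 dpi. Of 1126 olfactory receptors, 9, 4 and 1 had a peak at 3, 5 and 7 dpi and 1 in primary neurons, Olfr113 (fold enrichment 7.32, intergenic). Random lists of the same size gave 43.0, 37.9, 52.5 and 18.0 genes on average, length-matched lists 20.2, 18.7, 23.1 and 9.38, and draws of MEF peaks 15.9, 14.1, 20.1 and 7.17. At 1 dpi 4 had a peak against 3.42 in draws of MEF peaks, and in MEFs 884 did (percentile 99.5). Protocadherins, neuronal adhesion molecules, had no peak in 70 members at 5 and 7 dpi, where draws of MEF peaks gave 3.76 and 4.95. Against peaks at shuffled positions, counted within 2000 bp of the genes, olfactory receptors stood apart at 7 dpi (percentile 0.5), lay on the limit at 5 dpi (2.5) and did not stand apart at 1 or 3 dpi or in primary neurons, and protocadherins did not at 5 and 7 dpi (percentiles 8 and 13). Axon guidance genes had 3 of 59 members with a peak at 1 dpi (percentile 99.5, 96.8 when length-matched) and 6 at 3 dpi (98.4, 82.4). Voltage-gated ion channels had 6 of 43 at 7 dpi (99.0, 83.0) and pan-neuronal genes 3 of 30 in primary neurons (99.5, 97.6). None of these 4 counts stood apart from draws of MEF peaks, which gave 2.37, 9.39, 6.34 and 1.89 members, or from peaks at shuffled positions. In MEFs 13 of the 21 lists lay outside the central 95% of random lists, and 2 when peaks at shuffled positions were the comparison, where 1.05 per library are outside by chance.

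**Figure D2:**
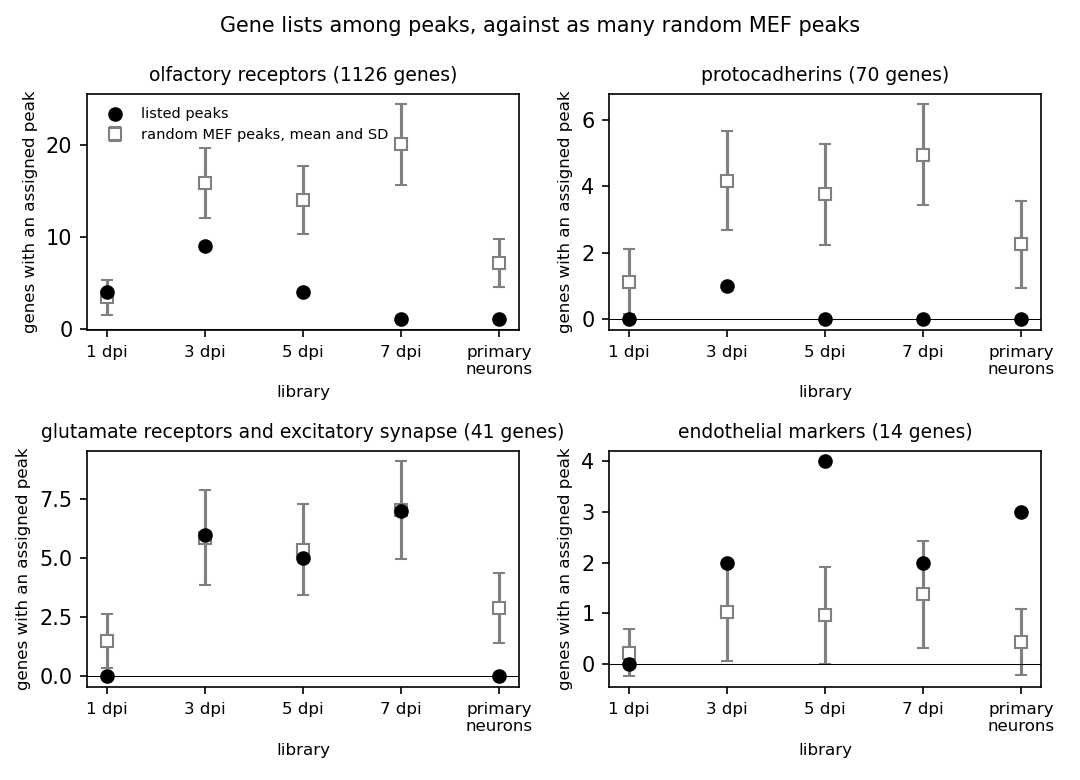
Genes with an assigned peak in 4 gene groups for the induced neurons and primary neurons, as points, with the mean and SD of 1000 random draws of as many MEF peaks. Olfactory receptors and protocadherins lie below the draws at 5 and 7 dpi, glutamate receptor genes lie close to them at 3, 5 and 7 dpi and below them in primary neurons (0 against 2.91), and endothelial markers lie above them at 5 dpi and in primary neurons.

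Peaks of induced neurons recurred at other days and in primary neurons. Of the 549 peaks of primary neurons, 69.6% (65.5 to 73.4) overlapped a peak at 7 dpi by at least 1 bp, 59.7% a peak at 5 dpi, 62.5% a peak at 3 dpi and 14% a peak at 1 dpi. Between neighbouring days, 43.1% (37.1 to 49.4) of the peaks at 1 dpi overlapped those at 3 dpi, 40.3% (37.6 to 43.1) of those at 3 dpi overlapped 5 dpi, and 63.2% (60.3 to 66.0) of those at 5 dpi overlapped 7 dpi. Shuffled peaks gave a mean of at most 0.474% in these pairs, and at most 1.15% in a single shuffle. Median tags at the summit were 40 to 46 in these libraries, but the highest summit held 149559 tags at 1 dpi and 1215308 at 5 dpi. Whether part of the recurrence has a technical source was not tested. Genes with an assigned peak in all 5 of these libraries numbered 56 of the 2066 with any, and included Prox1, a homeobox gene of neural development, and Dcc, the netrin receptor of axon guidance, both picked after their values were seen. Their strongest peaks were intergenic, 129.5 to 264 kb from the TSS for Prox1, where that at 7 dpi was at another place than the rest, and 421 to 423 kb for Dcc. On MEF peaks lay 41.6% (35.6 to 47.8), 38.0% (35.3 to 40.8), 43.7% (40.8 to 46.7) and 37.7% (35.3 to 40.1) of the peaks at 1, 3, 5 and 7 dpi and 52.5% (48.2 to 56.7) of those in primary neurons, against 7.25 to 8.29% on average when shuffled. With the MEF list limited to its strongest peaks, as many as the other library had, these shares fell to between 0.763 and 2.47%. Among peaks off the MEF list with at most 500 tags at the summit, the share of 5 dpi peaks on 7 dpi peaks was 51.3%, that of primary neurons on 7 dpi 48.6% and that of 1 dpi on 3 dpi 17.6%.

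Promoters within 2000 bp of a TSS were compared between each library and MEFs in the authors' lists, which call a region hyper where the other library had more reads and hypo where MEFs had more. Regions with fewer reads than MEFs outnumbered those with more in every comparison. The hyper and hypo regions numbered 3415 and 12287 at 1 dpi, 3239 and 11184 at 3 dpi, 5168 and 11138 at 5 dpi, 2204 and 11276 at 7 dpi, and 2136 and 11491 in primary neurons. The share hyper was 21.7% (21.1 to 22.4), 22.5% (21.8 to 23.1), 31.7% (31.0 to 32.4), 16.4% (15.7 to 17.0) and 15.7% (15.1 to 16.3) in that order. With p below 1e-10, which cut regions of both directions, hypo regions still outnumbered hyper ones in every comparison. Hypo regions held more reads, so this limit does not settle the direction either. Recentring and a limit on reads cannot test the direction of the split, as each cut regions of only 1 direction. Recentred on the median of all listed regions, with an absolute log2 of at least 1 required, the share hyper was 50.2, 46.9, 57.3, 39.4 and 39.5%. Since most listed regions were hypo, this kept every hyper region and cut only hypo ones, at 1 dpi from 12287 to 3392. With at least 15 reads in the higher library in both lists the share hyper was 2.48, 4.20, 7.35, 3.78 and 2.33%. Every hypo region already met that limit, so only hyper regions were cut. Hyper regions held at least 9 reads, with a median of 10 or 11, and had no MEF read in 91.2 to 96.2% of cases, whereas hypo regions held at least 15 MEF reads, with a median of 23 or 24. Of the genes in a hyper list, 41.0 to 47.0% were also in the hypo list of the same comparison, through another region. Of all background genes, 34.1 to 36.8% were in a hypo list.

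**Figure D3:**
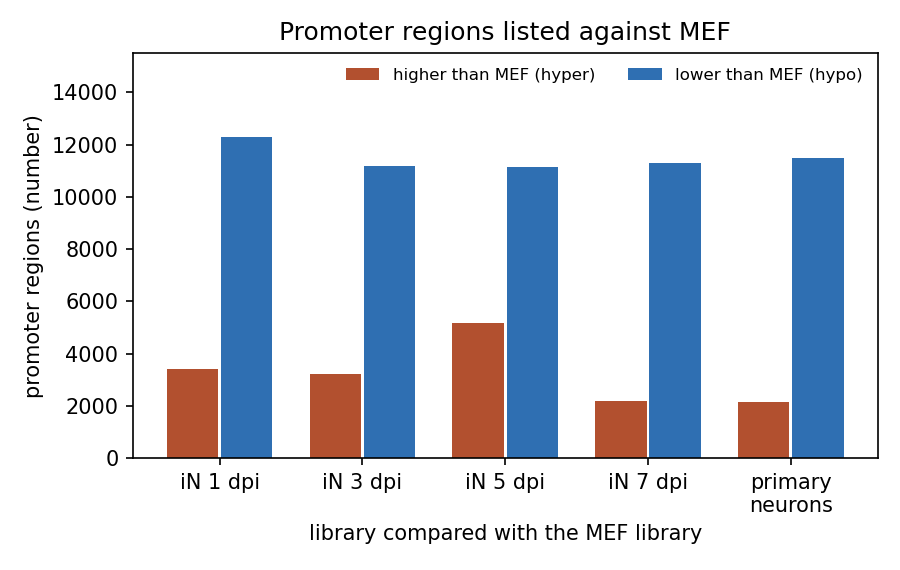
Hyper and hypo promoter regions in the 5 comparisons with MEFs, as bars from 0. Hypo regions number 11138 to 12287 and hyper regions 2136 to 5168.

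At 1 dpi the promoter of Esr1, the oestrogen receptor alpha gene, held 52 reads against 0 in MEFs, at least 30.8-fold higher, on chromosome 10 from 4613301 to 4613680. Spt1 had 31 reads against 1, a ratio of 55.1 with a counting interval of 9.18 to 2246, and Mill1, an MHC class I-like gene, 22 against 1. Speer7-ps1 (36 against 2) and Heatr6 (17 against 1) followed. Lower than in MEFs were the olfactory receptor Olfr461 (1 against 95, 53.6-fold, 9.36 to 2133), the serotonin receptor Htr6 (1 against 93, 52.4-fold, chromosome 4 from 139074701 to 139075340) and Cfp, which encodes the complement protein properdin (1 against 91), with Trim43c and Mppe1 next. Imprinted genes were in the hyper list in 10 of 35 cases, at percentile 99.5 of random lists, led by Zim1 (21 reads against 0, at least 12.4-fold higher), Peg10 (at least 7.11-fold), Snrpn (at least 6.52-fold) and the growth factor receptor Igf2r (at least 5.92-fold). Of 1126 olfactory receptors 201 were hyper, or 17.9%. Only 2 of 59 axon guidance genes were hyper, Sema3a and Sema3c (percentile 1.43), and Sema3b was at least 10.9-fold lower (0 against 58). Neurogenic transcription factors were hypo in 10 of 47 cases (percentile 1.12), among them Pax6, a regulator of eye and forebrain development (0 against 37, at least 6.94-fold lower). Pan-neuronal genes were hyper in 5 of 30 cases, with Tubb3, Ncam1 and Thy1 each at least 6.52-fold higher (11 against 0). Of the genes named for 1 dpi, Heatr6, Htr6, Ncam1, Sema3a and Snrpn were in both lists. Of the hypo regions 46.3% lay on a MEF peak and none on a peak of the 1 dpi library.

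At 3 dpi, Arl9, a small GTPase gene, held 39 reads against 1 in MEFs (67.9-fold, 11.5 to 2764, chromosome 5 from 77004581 to 77004820). Ttll2 had 30 reads (52.2-fold), Rspo3, which encodes a Wnt pathway ligand, 26, and the beta-defensin Defb28 25, each against 1. Fewer reads were found at Rad50, a DNA break repair gene (1 against 100, 57.3-fold, 10 to 2279, chromosome 11 from 53705201 to 53705940), at Eif2ak4, an amino acid sensing kinase (1 against 97), at Olfr461, at Pter and at Wtap, a subunit of the RNA methylation complex (1 against 78). Keratin and skin genes were hyper in 20 of 113 cases (percentile 98.5, and 96.8 against genes named in any list), such as Krtap5-3 (27 against 0, at least 15.7-fold) and Krt33a (26 against 0, at least 15.2-fold). Among fibroblast and extracellular matrix genes 6 of 54 were hyper and 22 hypo, neither count outside random lists. Their extremes were Cd44, the hyaluronan receptor (24 against 1, 41.8-fold higher, 6.85 to 1727), and S100a4 (0 against 54, at least 10.3-fold lower). Excitatory synapse genes with more reads included the NMDA receptor subunits Grin1 (20 against 0, at least 11.7-fold) and Grin2d (15 against 0, at least 8.75-fold). Neurogenic transcription factors were hypo in 9 of 47 cases (percentile 1.35), led by Lhx2 and Insm1. Arl9, Defb28, Pter, Krtap5-3, Krt33a, Cd44, Grin1 and Grin2d were in both lists. Of the hypo regions 49.7% lay on a MEF peak.

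At 5 dpi the hyper list was the longest of the 5. It was led by the pseudogene Pisd-ps2 (45 reads against 1, 78.3-fold, 13.4 to 3179, chromosome 17 from 3083581 to 3084320), the chromatin gene Dpf2 (36 against 1), the sperm acrosome gene Spaca3 (31 against 1), Parvg and Aldh1l1, an enzyme of folate metabolism used as an astrocyte marker (each 30 against 1, 52.2-fold). Lower were Usp53 (1 against 96, 55.0-fold), Star, which carries cholesterol into mitochondria (1 against 77, 44.1-fold, 7.67 to 1760), the GTPase gene Rab23 (1 against 72) and Prh1. Imprinted genes were hyper in 12 of 35 cases (percentile 99.3), such as Mest (23 against 0, at least 13.4-fold, chromosome 6 from 30733161 to 30733620), Slc22a18 (at least 8.75-fold) and the neighbours Dlk1 and Meg3 (each at least 7.58-fold). Microglia and blood markers were hyper in 7 of 18 cases (percentile 98.7), with Spi1, listed as Sfpi1 and a regulator of blood cell fate (31 against 0, at least 18.1-fold), Hba-a1 and Tmem119 (each at least 10.5-fold). Pluripotency and germline genes were hyper in 10 of 31 cases (percentile 98.2), with Nanog (29 against 0, at least 16.9-fold), Tex101 (at least 7.58-fold) and Utf1 (at least 6.42-fold). Against a background of genes named in any list, these percentiles were 92.7 for microglia and blood and 85.9 for pluripotency. Inhibitory synapse genes were hyper in 1 of 29 cases, Gabbr1 (percentile 1.83). Pisd-ps2, Spaca3, Star, Rab23, Mest, Meg3, Hba-a1 and Tex101 were in both lists. Of the hypo regions 49.7% lay on a MEF peak.

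At 7 dpi, Ttll2 held 44 reads against 1 in MEFs (76.6-fold, 13.1 to 3110, chromosome 17 from 7353181 to 7353980) and Caly, a neuronal vesicle protein gene, 38 against 1 (66.1-fold). Efcab6 (34 against 1), Aldh1l1 (32 against 1, 55.7-fold) and Spt1 (30 against 1) followed. Lower were the tight junction gene Inadl (1 against 99, 56.7-fold, 9.92 to 2257, chromosome 4 from 98544281 to 98545200), Ceacam14 (1 against 82), the bitter taste receptor Tas2r118 and Endou (each 1 against 81) and Star (1 against 77). Keratin and skin genes were hyper in 16 of 113 cases (percentile 99.2), such as Krt77 (19 against 0, at least 11.1-fold). Olfactory receptors were hyper in 67 of 1126 cases (percentile 2.1). Imprinted genes were hyper in 1 of 35 cases, Meg3 (9 against 0, at least 5.25-fold). Pan-neuronal genes were hyper in 4 of 30 cases and hypo in 11, within the range of random lists. Those with more reads were the synaptic genes Syp (10 against 0, at least 5.83-fold) and Syn2, the neurofilament gene Nefm and Thy1 (each 9 against 0, at least 5.25-fold). The collagen gene Col5a2 had fewer (1 against 52, 29.8-fold, 5.10 to 1196). Efcab6, Star, Meg3 and Nefm were in both lists.

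In primary neurons, Pisd-ps2 and Rcvrn, which encodes the photoreceptor protein recoverin, each held 26 reads against 1 in MEFs (46.5-fold, 7.69 to 1918, Rcvrn on chromosome 11 from 67694121 to 67694620). Sp110 (24 against 1), Nudt13 and Mrrf, a mitochondrial translation gene (each 23 against 1), came next. Lower were Olfr461 (1 against 95, 52.8-fold), Star (1 against 77, 42.8-fold), Olfr1247 (1 against 73), Trmt61b and Fut8, a fucosyltransferase gene (each 1 against 71). Pan-neuronal genes were hyper in 2 of 30 cases, Gap43 and Syt1 (each 9 against 0, at least 5.40-fold), and hypo in 12. Both genes were also hypo in another part of the promoter, Gap43 with 1 read against 44, and Pisd-ps2, Rcvrn, Nudt13 and Mrrf were in both lists too. Among fibroblast genes 3 of 54 were hyper and 19 hypo, such as the fibronectin gene Fn1 (0 against 39, at least 7.22-fold lower). Synapse genes with fewer reads included Grin2d (1 against 63, 35.0-fold, 6.06 to 1405). None of these groups stood apart from random lists.

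Olfactory receptors were hypo more often than random genes in all 5 comparisons, in 545, 534, 530 and 540 of 1126 cases at 1, 3, 5 and 7 dpi and 552 in primary neurons, or 47.1 to 49.0%, at percentile 100 each time. In all 5 comparisons 396 of them were hypo. The comparisons share the MEF library and most of their hypo regions, so these are not 5 independent findings. Olfactory receptors are arranged in clusters, which random lists of single genes do not keep. Comparisons matched on gene length or with shuffled positions were run for peaks only. Neurogenic transcription factors were hypo in 9 to 11 of 47 cases, and 8 of them in all 5, among them Bcl11b, Insm1, Lhx2, Lhx6, Pax6, Prox1 and St18, of which Lhx6, Prox1 and St18 were also hyper in at least 1 comparison. Their percentiles of 1.12 and 1.35 at 1 and 3 dpi became 19.7 and 17.9 against genes named in any list. In all, 10 of 105 hyper and 7 of 105 hypo counts lay outside the central 95% of random lists, where the width of the range gives 5.25 each by chance. In the test on simulated data 7.5% of random lists fell outside it, a larger share than these hypo counts make up. Against genes named in any list the hyper counts outside turned from 7 above and 3 below to 4 above and 6 below, as olfactory receptors became low at 3 and 5 dpi and in primary neurons (percentiles 0.01, 0 and 0.01).

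The other gene groups did not stand apart in any of the 5 comparisons. Hox genes were hypo in 37.8 to 42.2% of cases, cell cycle genes in 35.7 to 40.5%, housekeeping genes in 39.3 to 42.9%, glutamate receptor and excitatory synapse genes in 39.0 to 43.9%, voltage-gated ion channels in 30.2 to 39.5%, protocadherins in 28.6 to 32.9% and skeletal muscle genes in 31.0 to 34.5%. Endothelial markers were hypo in 35.7 to 57.1%, astrocyte markers in 25 to 37.5% and oligodendrocyte markers in 28.6 to 42.9%. Their shares in the hyper lists were at most 20, 9.52, 14.3, 26.8, 23.3, 17.1, 24.1, 35.7, 18.8 and 28.6% in the same order.

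Genes of the DNA modification machinery were in the hyper lists in 3 to 7 of 33 cases and in the hypo lists in 10 to 12, within the range of random lists. Tet2, which encodes an enzyme that makes 5-hydroxymethylcytosine, had more reads than MEFs at 3, 5 and 7 dpi and in primary neurons, with 9, 20, 9 and 10 reads against 0, or at least 5.25, 11.7, 5.25 and 6-fold. The regions lay on both sides of the TSS on chromosome 3, that at 5 dpi from 133545441 to 133545900. Tet1 had fewer at all 4 days (0 against 17, at least 3.19-fold lower at 1 dpi and 3.24-fold at the others) and Tet3 more at 7 dpi only (9 against 0, at least 5.25-fold). The DNA methyltransferase Dnmt1 had more at 1 and 3 dpi (at least 5.33 and 6.42-fold) and Idh1, a source of the cofactor of the TET enzymes, at 3 and 5 dpi and in primary neurons (at least 8.17, 8.17 and 5.40-fold). Gadd45a (10 against 0 at 3 dpi) and Smug1 (9 and 10 against 0 at 5 and 7 dpi), both linked to DNA repair, were hyper too. Dnmt3a, Mbd3, Gadd45b, Ung, Mbd1 and D2hgdh were hypo in all 5 comparisons, and Dnmt3a, Mbd1 and D2hgdh also had a hyper region in at least 1 of them. Dnmt3l was hypo at 1, 3 and 7 dpi and in primary neurons, Apobec1 at 1, 5 and 7 dpi and in primary neurons, and Zbtb33 at all 4 days, and each had a hyper region at 1 or 5 dpi. In no promoter list were 15 members, among them Tdg, Uhrf1 and Dnmt3b. Thy1 was hyper at 1, 3 and 7 dpi, Snai1 at 1 dpi, and Twist1, a mesenchymal transcription factor, hypo at 1, 3 and 5 dpi (0 against 16, at least 3 to 3.05-fold lower). Pou3f2, Myt1l, Neurog2, Sox11, Map2 and Col1a1 were in no promoter list.

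Few genes kept a hyper promoter through the days, and many kept a hypo one. Hyper at all 4 days were 141 genes, where independent lists of these lengths would share 4.23, and 82 were also hyper in primary neurons. Of 8804 genes hyper at any day, 6144 were so at a single day. Hypo at all 4 days were 6881 genes (386 for independent lists), and 6481 were also hypo in primary neurons. Without genes that were in both lists of a comparison, 55 and 29 genes were hyper, and 4068 and 3610 hypo, in the same order. The genes hyper in all 5 with the largest smallest fold were Sp110, Speer7-ps1, Speer4e, Siglecg, Pisd-ps2, Pisd-ps1, Allc, Prmt10, Sp140 and Taar1. Of these, Pisd-ps1, Pisd-ps2 and Taar1 were also hypo in all 5 comparisons, Allc, Prmt10 and Siglecg at 1 dpi and Speer7-ps1 in primary neurons. Several belong to families with near-identical copies, so their reads could be split between copies. Taar1, a trace amine receptor, had 0 MEF reads throughout and was at least 9.48, 21.0, 9.33 and 15.8-fold higher at 1, 3, 5 and 7 dpi and 7.2-fold in primary neurons (chromosome 10 from 23918741 to 23919280 at 3 dpi). Allc, an allantoicase gene, was at least 8.30, 13.4, 9.33, 15.2 and 9-fold higher. The hypo genes chosen likewise were Olfr1020, Olfr527, Phlpp2, Amy1, Glb1, Rftn1, Shmt2, Zscan4b, Crx and Olfr1355, of which Olfr527, Amy1, Rftn1, Zscan4b, Crx and Olfr1355 were also hyper in at least 1. Olfr1020 had 1 read in each library against 47 in MEFs at the same place (chromosome 2 from 85849261 to 85849640), 26.1 to 26.9-fold lower.

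Neighbouring comparisons shared promoter regions of both kinds. Of the hyper regions, 8.32% at 1 dpi overlapped those at 3 dpi, 21.8% at 3 dpi those at 5 dpi, 13.9% at 5 dpi those at 7 dpi and 15.6% at 7 dpi those of primary neurons, against 1.31 to 3.32% for regions placed at random around TSSs. Of the hypo regions 80.9, 83.5, 84.6 and 85.1% did, against 8.17 to 8.53%. Between 5 and 7 dpi 909 hyper genes were shared where independent lists would share 330.5. In neighbouring pairs the shared genes were 1.85 to 3.10 times as many as independent lists give for hyper and 2.50 to 2.57 times for hypo lists. Against a background of genes named in any list the ratios were 1.09 to 1.82 and 1.48 to 1.52. Unchanged libraries simulated around the MEF reads gave at most 14 hypo calls in 36861 regions and no hypo call in both comparisons of a pair. Such draws leave out error in the MEF reads themselves. They gave no hyper call in 15988 regions, but this outcome was largely fixed in advance. Most of these regions had no MEF read, and a draw around 0 reads is always 0. With the MEF reads drawn too, at rates of 1 to 60 reads, the Poisson chance of a call in both comparisons was at most 0.0175% for a hypo and 0.000164% for a hyper region. Error of the MEF library beyond Poisson counting is not covered, and that library could not be split, so part of the excess may come from the shared control.

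**Figure D4:**
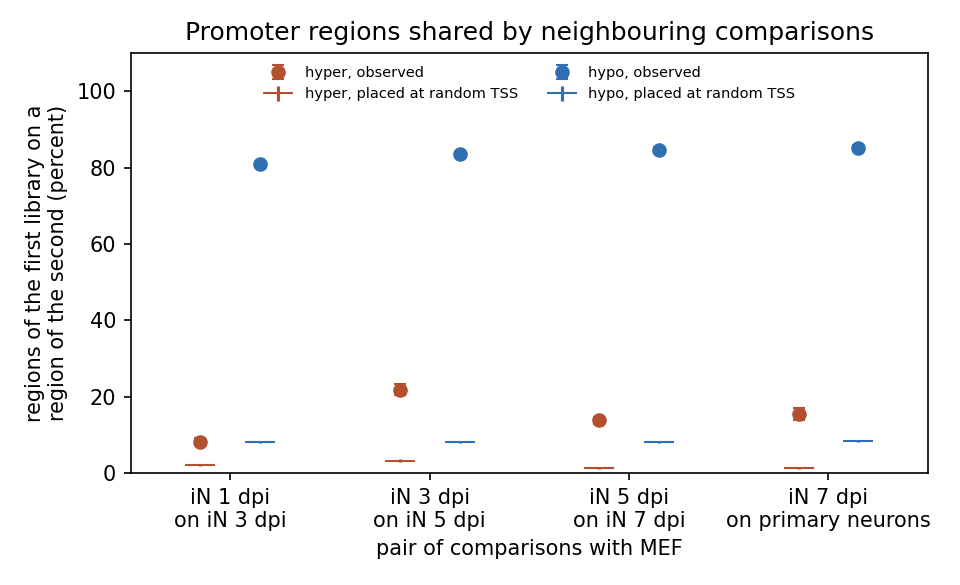
Share of promoter regions that overlap those of the next comparison, hyper and hypo, as observed values with exact 95% intervals beside the mean and SD of regions placed at random TSSs. Hypo regions overlap in 80.9 to 85.1% of cases and hyper regions in 8.32 to 21.8%.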

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

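No tests were run in this part. Between 7 dpi and primary neurons, 90 genes were hyper against MEFs at 7 dpi and hypo in primary neurons, and 75 were the reverse, leaving out genes in both lists of a comparison. With such genes kept, 885 and 886 genes were in these opposite lists, where independent lists of these lengths would share 680 and 668. They drew attention because the lists are opposite in the 2 groups. In the genes named below the folds come from different regions with different MEF reads, so no single place is compared between the groups. The differences themselves were not tested.

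With 0 reads held at the floor, Bc1 had the largest value. At Bc1, a brain cytoplasmic RNA gene, a region held 29 reads at 7 dpi against 1 in MEFs (50.5-fold, 8.41 to 2073). Another held 1 read in primary neurons against 26 (14.5-fold lower, 2.37 to 592), which gave a log2 difference of 9.51. With counting intervals this wide, the size of that difference is uncertain. Trim65 had 7.94 (11 reads against 1, and 1 against 23). Spdef, a transcription factor of secretory epithelium, had at least 7.43 (14 against 0, and 1 against 38), and Lrrc4b, a synaptic adhesion gene, had at least 7.40 (20 against 0, and 1 against 26). The order of these 3 is therefore open. Sp6, a transcription factor of tooth and skin development, had 7.2 (39 against 4, and 2 against 31). At Bc1 the 7 dpi region lay on chromosome 10 from 80368261 to 80368660 and that of primary neurons from 80368061 to 80368340. The regions also overlapped in part at Spdef and Lrrc4b, and lay apart in the same promoter at Trim65 and Sp6. No explanation was weighed for these genes.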

How the results depend on the processing

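Of the values that answer a comparison, 91 stayed within 1.5 times a count or within the 95% interval of a share under an alternative setting, 107 moved and 2 reversed. The reversals were the split of hyper and hypo regions at 1 and 5 dpi, where hyper regions made up 50.2 and 57.3% after recentring. That setting kept every hyper region and cut only hypo ones, so these reversals follow from it and do not bear on the direction. At 1 dpi it left a near even split, 3415 hyper against 3392 hypo regions. Without the submitters' scaling each fold of a comparison changes by the same factor, 1.75 to 1.80, which could not reverse any. Of the folds of named genes, 188 stayed within their counting interval and 55 did not. Limits include low depth, since hyper regions hold a median of 10 or 11 reads, and the single library per group. The tests with at least 15 reads, without scaling, without peaks over 500 tags, without multi-copy loci, without peaks on MEF peaks, and against shuffled or MEF peaks were chosen after the results were seen. Autosomes only, merging within 1000 bp, gene symbols in place of regions and leaving out multi-copy loci moved no count of peaks or regions by over 1.5 times, whereas sharing between comparisons differed between genes and positions. No paired analysis was possible because each group had 1 library. Random lists matched on promoter CpG content were not run. Stricter settings keep fewer peaks or regions by construction, and for other moves the cause was not tested.

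With fold enrichment of at least 10, 1808 MEF peaks, 2, 11, 20 and 49 at 1, 3, 5 and 7 dpi and 10 in primary neurons were left. The promoter share was then 1.94% in MEFs, 2.04% at 7 dpi and 0 at 1, 3 and 5 dpi and in primary neurons. The share on MEF peaks was 50% at 1 dpi, 25% at 5 dpi, 14.3% at 7 dpi and 30% in primary neurons, and 100% of 1 dpi peaks lay on 3 dpi peaks, 36.4% of 3 dpi on 5 dpi and 75% of 5 dpi on 7 dpi. A −log10 q of at least 27.9 left 17993 peaks in MEFs, 44, 181, 200 and 268 at the 4 days and 112 in primary neurons. With 50% of a peak covered, the shares on MEF peaks were 35.5, 28.4, 33.2, 28.2 and 41.5% in the order 1, 3, 5 and 7 dpi and primary neurons. With the MEF list limited to as many peaks they were 0.763, 1.94, 2.18, 2.47 and 2.004%. Without peaks over 500 tags, 32.6% of 1 dpi peaks lay on MEF peaks and 36.8% on 3 dpi peaks, and 64.8% of primary neuron peaks on 7 dpi peaks.

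In the same order, p below 1e-10 left 26, 66, 143, 115 and 35 hyper and 639, 472, 454, 510 and 506 hypo regions. At least 15 reads left 313, 490, 883, 443 and 274 hyper regions. An absolute log2 fold of at least 2 left 6968, 6598, 6508, 6668 and 6615 hypo regions, and recentring left 3392, 3663, 3844, 3396 and 3273. The share hyper was 46.9, 39.4 and 39.5% at 3 and 7 dpi and in primary neurons after recentring, and 2.48, 4.20, 7.35, 3.78 and 2.33% in the 5 comparisons with at least 15 reads. Recentring cut only hypo regions and the limit of 15 reads only hyper ones, so these shares follow from the settings.

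For the pairs 1 and 3, 3 and 5, 5 and 7 dpi, and 7 dpi and primary neurons, sharing was 1.85, 2.23, 2.75 and 3.10 times that of independent lists for hyper genes and 2.50 to 2.57 times for hypo genes. Over that of placed regions it was 4.05, 6.58, 9.83 and 11.9 for hyper and 9.76, 10.2, 10.2 and 9.98 for hypo regions matched by position. Over independent lists it was 4.02, 4.09, 4.09 and 4.08 for hypo genes at an absolute log2 fold of at least 2. With a background of named genes it was 1.09, 1.31, 1.62 and 1.82 for hyper and 1.48, 1.51, 1.52 and 1.51 for hypo genes.

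Among peaks, the number of gene lists that stood apart was 13 in MEFs, 1, 3, 4 and 4 at the 4 days and 3 in primary neurons. Against shuffled peaks it changed to 2 in MEFs, 0 at 1 dpi, 1 at 3 dpi, 2 at 7 dpi and 1 in primary neurons. With length-matched lists it changed to 0, 1 and 2 at 1, 3 and 7 dpi, and against draws of MEF peaks to 0 and 1 at 1 and 3 dpi. Without peaks on MEF peaks it changed to 0, 1 and 2 at 1, 3 and 7 dpi. The lists counted were not always the same. Against shuffled peaks, DNA modification machinery at 3 dpi (percentile 99.5) and skeletal muscle at 7 dpi (98.0) were new. Against draws of MEF peaks, protocadherins at 3 dpi (1.65) were new. Without genes in both lists of a comparison, 55 genes were hyper at all 4 days and 29 also in primary neurons, and 4068 and 3610 were hypo.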

Other observations

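Tests of copied fragments, of the MEF library in both promoter patterns and of depth in the hypo promoters were chosen after the results were seen, as were the draws of MEF peaks.

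Some neuronal gene groups had fewer assigned peaks than draws of as many MEF peaks would give. At 7 dpi 1 of 30 pan-neuronal genes had a peak against 4.55 on average in the draws, and 5 of 59 axon guidance genes against 11.3. Voltage-gated ion channels had 1 of 43 members at 5 dpi against 4.81, and glutamate receptor and excitatory synapse genes none of 41 in primary neurons against 2.91. Among random lists of the same size these counts were not low, at percentiles 41.3, 90.0, 40.2 and 26.2, and at 7 dpi glutamate receptor genes (7 against 7.05) and ion channels (6 against 6.34) were close to the draws. Against shuffled positions axon guidance genes had few peaks at 5 dpi (1 against 5.72, percentile 0.5) and lay on the limit at 7 dpi (3 against 8.88, percentile 2.5), and the other 3 counts did not stand apart. A 7 dpi peak assigned to Neurog2, a transcription factor of neuronal fate picked after its values were seen, lay 65.3 kb away (fold enrichment 6.04) and thus outside the gene.

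The MEF library listed over 100 times as many peaks as any other, 176853 in all. A deeper MEF library is argued against if the submitters' scaling gives the depth, since 45183 MEF peaks were left at a minimum of 46.8 tags, 28.6 times the 1579 of the longest other list. Peaks scattered without regard to genes remain open, as MEF summits lay near a TSS 0.968 times as often as shuffled ones (3.24% against 3.35%), though a similar share over gene bodies had been seen before. Piles of copied fragments stay open as well: among peaks of 40 to 60 tags 81.6% had the shortest length, 2.06 times the highest share elsewhere (39.6% at 1 dpi), but the excess of short peaks had been seen before and duplicates were not counted. A real difference between fibroblasts and the other cells stays open too and was not tested. Which input, that of MEFs or the mixed one, was used for each peak list was not given, so its part could not be weighed.

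Hypo promoters were largely the same places in the 5 comparisons, which share the MEF library. Lower depth of the other libraries was tested only in part. The promoter signal was already scaled, so at the depth that the submitters' scaling gives the test covers counting error alone. Unchanged regions would then share at most 10.8% of their hypo calls with a second comparison, whereas at least 80.2% were shared. The limit holds at MEF rates of 1 to 60 reads where a call has a chance of at least 1e-06. Counting error at that depth is thus argued against. A depth that differs from the scaling was not tested and stays open. A MEF library that by itself sets the hypo lists may explain the sharing, with a median of 83.8% of hypo and 12.5% of hyper regions shared, a ratio of 6.69. List lengths alone would give 4.06, so this explanation and a loss of the mark at the same promoters cannot be told apart with 1 MEF library.

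Hyper promoters were shared by 3, 5 and 7 dpi beyond random placing. Multi-copy loci stay open. Regions with any MEF read, with a high number of reads or at a locus listed for several genes were left out. Of the 4800 regions then left at 5 dpi, 10.9% still overlapped those at 7 dpi, 8.94 times the 1.22% (SD 0.183) of placed regions. This filter does not measure copies, and near-identical copies without MEF reads pass it, so it cannot decide. The shared MEF library as the whole cause was not decided. Hyper regions of 3 and 5 dpi lay on those of 7 dpi 1.41 and 1.58 times as often as on those of primary neurons (13.9% against 8.77% at 5 dpi). At 1 dpi, outside the pattern, the ratio was 1.17. The lists of 7 dpi and primary neurons were of similar length, 2204 and 2136 regions. They differed in strength, with 443 and 274 regions of at least 15 reads, so a cause in the MEF library need not give equal shares. The bounds of this test were also set after the values were seen. The sharing was not particular to induced neurons, since 7 dpi regions overlapped those of primary neurons 11.9 times as often as placed regions, against 9.83 times for 5 on 7 dpi. The MEF library, as the whole cause or a part of it, and common handling of the libraries stay open, and no biological explanation was tested.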
